A study of Homo sapiens with 15 samples.

How the data were processed

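The data are bulk RNA-seq of U87 and U251, a pair of established human glioma cell lines. The labels name 15 libraries in 5 groups of 3: U87 control, U87 with hairpin 1812, U251 control, U251 with hairpin 1812 and U251 with hairpin 1813. The hairpins are short hairpin RNAs (shRNAs) against LAMP2A, the isoform of LAMP2 that serves as the receptor of chaperone-mediated autophagy, and the knockdown cells were stably transfected. The controls are labelled wild type and no control hairpin or empty vector is named. The libraries were described as made from total RNA depleted of ribosomal RNA, with random primers and strand marking by dUTP. More than 1 RNA extraction method and more than 1 sequencer are named without saying which library each belongs to.

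Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, trimmed with cutadapt 1.9.1, aligned to GRCh38 with HISAT2 2.0.1 and counted per gene with HTSeq 0.6.1. The notes also name bedtools 2.17.0 and DESeq2 without a version. The counting strand and the annotation release were not given in the sources used here. The deposited table gives a count and an FPKM value for each of 60612 genes in each library, with position, exonic length and symbol. FPKM recomputed from the counts and the exonic lengths matched the deposited FPKM within 0.005. Gene positions in the text are those of the deposited table, in GRCh38. Of its gene IDs, 58394 occur in GENCODE 29, which supplied the biotypes, and 44979 have the same start and end there.

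The test was edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, the filterByExpr filter and quasi-likelihood tests, two-sided, with Benjamini-Hochberg adjustment over genes within each comparison. Limma on FPKM was foreseen for the case that no counts were given. All 15 libraries entered a single fit with 5 group means, which left 16841 genes, 10 residual degrees of freedom, 4.52 prior degrees of freedom and a common biological coefficient of variation of 0.2255. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. SE is the standard error of the log2 fold change, taken as its absolute value divided by the square root of the F statistic. CPM values are read counts scaled to the TMM-adjusted library size, given as mean ± SD of 3 libraries. Fold changes of genes with 0 counts in a group are given as lower bounds against a floor of 3 counts over the group. Genes with 1 to 3 counts in a group are given as ratios with an exact 95% interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

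The 6 comparisons were the 3 knockdown groups against the controls of their line, U251 control against U87 control, hairpin 1812 against 1813 in U251, and the difference between the effects of hairpin 1812 in U87 and in U251. These, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined, apart from those described as chosen later. The rule names LAMP2 in every comparison. For each knockdown comparison it names the 8 largest and 8 smallest log2 fold changes among genes at an adjusted p under 0.05 with a mean of at least 5 FPKM in the higher group, a symbol, and all 3 knockdown libraries on the same side of all 3 controls. For the other comparisons it names 5 in each direction, and for each list that passed, up to 4 members with the smallest adjusted p in the direction of the list. A preference for protein-coding genes applied only if the table gave a biotype, which it does not. Genes of chromosome Y that the rule names are not reported here. Genes named in the text beyond this rule were chosen after their values were seen, and are introduced as such.

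Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over lists within a comparison, and again with an estimated correlation. Of 810 list members 749 were tested. Some members of the lists are not reported here by name, and they stayed in the tests. A list's count of members is given over all genes tested and adjusted over the list alone. The list tests between the control lines were added after seeing the data. DESeq2 1.42.0 served as another tool. In a self-test with known changes put into simulated counts, 44% to 58% of genes changed 2-fold and 92% to 93% of genes changed 4-fold were recovered at an adjusted p under 0.05 across the 3 knockdown comparisons. At most 4.83% of passing genes were unchanged ones. The self-test drew the libraries of a line from the mean of its controls, without the difference among control replicates described below. The share of unchanged genes therefore does not carry over to the real calls.

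The labels do not say whether replicates are separate cultures, so p-values measure only the spread between libraries. In every group replicates 2 and 3 were closer to each other than to replicate 1. A chi-square per gene, where counting noise alone gives about 1, was 1.87 between U87 control replicates 2 and 3. It was 212 and 226 between these and replicate 1. In U251 control the same values were 2.72, 72.0 and 77.1. A group of 3 libraries may thus hold fewer than 3 independent samples, so SEs and p-values may be too small. Replicate numbers were not stated to pair libraries. After the groups' means were removed, libraries of the same number correlated above 0.1 in all 3 pairs for U251 control with hairpin 1813 (0.389, 0.197 and 0.240) and for the controls of both lines (0.422, 0.263 and 0.318), so values from a replicate block are given where they change a call. Libraries of the same number shared less in U87, at 0.0247, -0.0923 and 0.123 for control with hairpin 1812.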

Results

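Gene expression was measured by RNA-seq in 15 libraries of the glioma lines U87 and U251, with 3 libraries in each of 5 groups: U87 control, U87 with the shRNA 1812, U251 control, and U251 with the shRNA 1812 or 1813. The shRNAs target LAMP2A. The study compares cells with and without them to ask what loss of this receptor of chaperone-mediated autophagy changes in glioma cells. Total counts ranged from 14002652 to 18924072 per library. They were 16848617, 14080885 and 15744734 in U87 control and 16851461, 18924072 and 14763974 in U87 with hairpin 1812. In U251 they were 16889558, 18567878 and 16160504 in control, 14711011, 14002652 and 14163535 with hairpin 1812, and 15387704, 14639030 and 14605968 with hairpin 1813.

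LAMP2 (ENSG00000005893, chromosome X, 120426148 to 120469365) fell in U251 with hairpin 1812 and did not change detectably in U87 with the same hairpin. In U251 its level was 694 ± 29.9 CPM in control libraries (SD, n = 3) and 319 ± 7.51 CPM with hairpin 1812, a loss of 54.0% (log2 fold change -1.12, SE 0.15, adjusted p 0.00353, 95% interval -1.44 to -0.80). With hairpin 1813 it was 402 ± 15.3 CPM, 42.0% below control, with every library below every control. This missed the threshold (log2 fold change -0.79, SE 0.15, adjusted p 0.0907). It passed in 5 of the 21 alternatives: DESeq2 (-0.81, adjusted p 1.6e-05), no filter on low counts (adjusted p 0.0183), control replicate 1 alone (-0.71, adjusted p 0.031), the compared groups alone (adjusted p 0.0377) and without U251 control replicate 1. The difference between the hairpins at LAMP2 did not pass (log2 difference -0.33, adjusted p 0.772) except in a fit of those groups alone (adjusted p 0.0325). In U87 the control libraries held 195, 294 and 292 CPM and the hairpin 1812 libraries 257, 256 and 289 CPM (log2 fold change 0.04, SE 0.15, adjusted p 0.892, 95% interval -0.28 to 0.36), so the largest loss the interval allows is 17.6%. Against U87 control replicate 1 alone LAMP2 was higher with the hairpin (log2 fold change 0.45, adjusted p 0.0215). The effect of hairpin 1812 on LAMP2 differed between the lines by 1.16 log2 units (SE 0.21, adjusted p 0.00931). Exact two-sided permutation tests on log2 FPKM gave p of 1 in U87 and 0.1 for each hairpin in U251, and 0.1 is the smallest p that the 20 arrangements of 3 against 3 libraries can give. Counts cover the whole gene and do not separate LAMP2A from the other isoforms. LAMP1, the related lysosomal membrane gene, was chosen after its values were seen and averaged 559 CPM in U87 control, 472 CPM in U87 with hairpin 1812, and 298, 275 and 263 CPM in U251 control, hairpin 1812 and hairpin 1813.

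**Figure D1:**
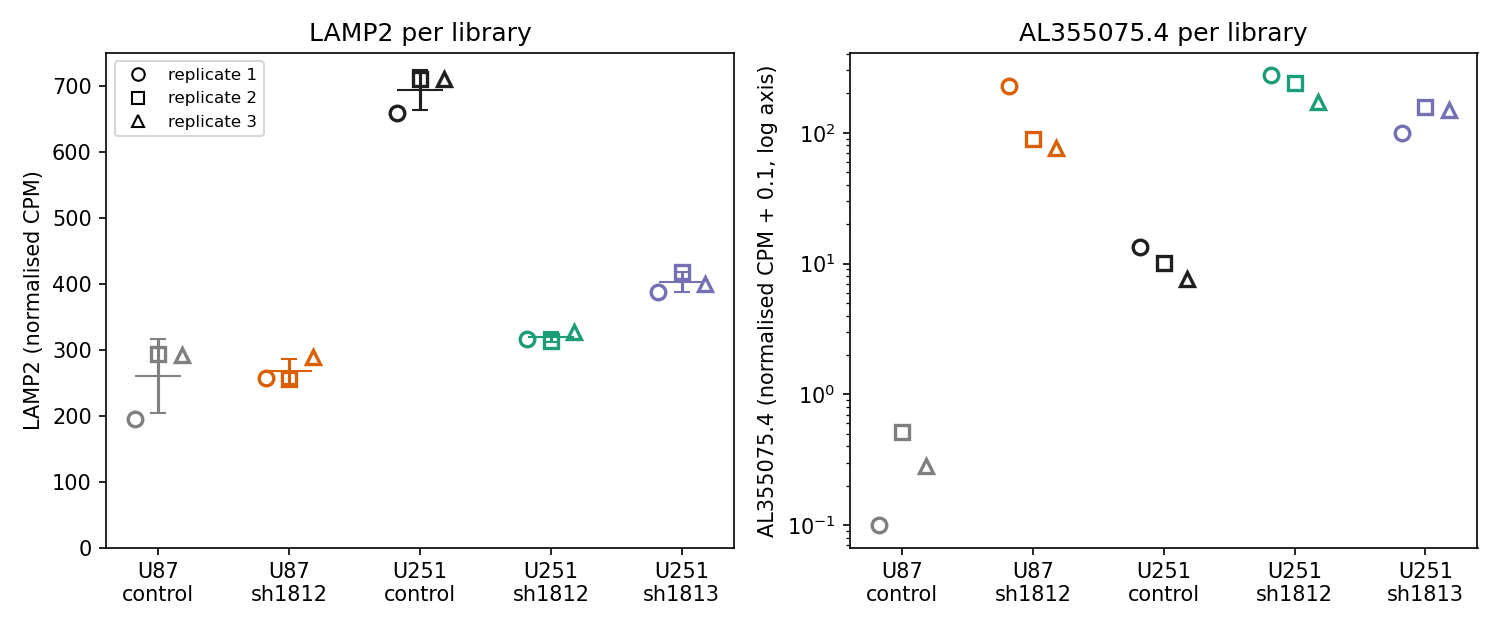
Normalised CPM of LAMP2 (left, linear axis, lines and bars are mean ± SD of 3 libraries) and of AL355075.4 (right, CPM + 0.1 on a log axis) in each library, by group, with the replicate number as marker shape. LAMP2 lies between 314 and 419 CPM in the U251 hairpin libraries and between 659 and 711 CPM in the U251 controls, while the U87 groups overlap.

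The control libraries did not form a uniform background. Control replicates 2 and 3 of both lines carried more counts on long and non-coding genes than the other 11 libraries. Their count-weighted mean exonic gene length was 6.53 to 6.77 kb against 5.61 to 5.92 kb. The nuclear RNA MALAT1 reached 250.7 to 391 CPM against 32.7 to 101 CPM, and NEAT1 643 to 906 CPM against 75.6 to 289 CPM. Counts on lincRNA genes made up 0.486% to 0.546% of the total against 0.256% to 0.415%. This set of differences is called library type below, although no label states its source. Between control replicate 1 and control replicates 2 and 3, 5464 genes differed over 2-fold in U87 and 1556 in U251. These differences correlated between the lines (Pearson r 0.42 across genes, which are not independent replicates). Within the knockdown groups the same split gave 1158, 574 and 886 genes. For this reason values against control replicate 1 alone, an alternative chosen after seeing the data, are given for the lists and for the genes of the naming rule whose results they end or reverse. Lists with a larger shift under that alternative are mostly not given. Mitochondrially encoded transcripts in U87, for example, had a median of 1.26 there and 0.06 with all controls. Cholesterol synthesis genes in U251 had medians of -0.52 with hairpin 1812 and -0.56 with 1813 there, against -0.20 and -0.13.

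**Figure D2:**
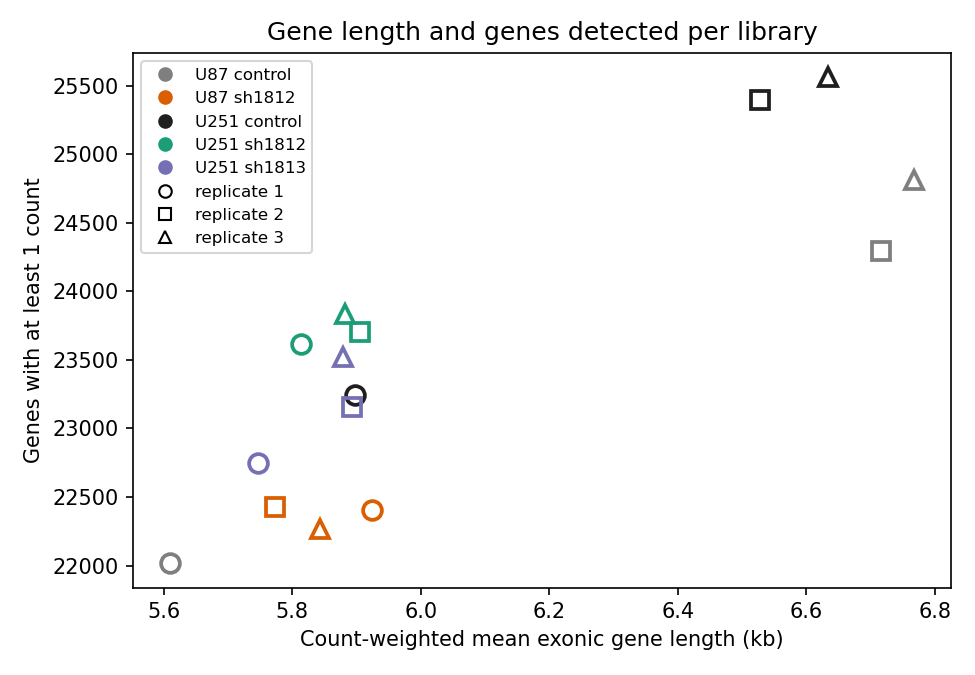
Number of genes with at least 1 count against the count-weighted mean exonic gene length (kb) of each of the 15 libraries, coloured by group, with the replicate number as marker shape. Control replicates 2 and 3 of U87 and U251 lie at 6.53 kb or more, and the other 11 libraries at 5.92 kb or less.

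In U87 with hairpin 1812, LAMA4 and EFEMP1 rose, 11 of 30 DNA replication genes and 4 of 31 mitosis genes rose by smaller amounts, and 6 of 25 p53 targets fell. EFEMP1, an extracellular matrix glycoprotein, rose from 2.77 ± 2.54 to 55.3 ± 0.536 CPM (n = 3 and 3, log2 fold change 4.32, SE 0.41, adjusted p 1.4e-04). LAMA4, a laminin chain of basement membranes named after its values were seen, rose from 16.7 ± 1.11 to 96.9 ± 8.07 CPM (log2 fold change 2.53, SE 0.13, adjusted p 1.9e-07). CHRDL1, a secreted BMP antagonist, rose from 3.21 ± 2.94 to 31.2 ± 5.76 CPM (log2 fold change 3.28, SE 0.43). In total 350 genes were called higher and 794 lower, and 987 and 1304 passed the adjusted p alone. These counts rest on the controls. Without U87 control replicate 1 they were 1348 and 2129, without control replicate 2 188 and 327, and without control replicate 3 194 and 349. Without a hairpin library they were as low as 224 higher (without replicate 1) and 428 lower (without replicate 3, against 483 and 463 without replicates 1 and 2).

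Further genes with large gains were the RNA-binding splicing regulator CELF2 (8.60 ± 13.5 to 67.7 ± 9.35 CPM, log2 fold change 2.98, SE 0.82) and the unnamed transcript AC109635.7 (log2 fold change 3.41, SE 0.87). The acute-phase gene SAA2 and the protease inhibitor SLPI passed at log2 fold changes of 7.58 (SE 1.69) and 3.17 (SE 0.88). SAA2 stood at 26.8 ± 44.7 CPM with an SD above its mean, and neither passed against control replicate 1 alone (adjusted p 0.085 and 0.226). Among genes that met the naming rule, the largest losses were EMILIN2, an elastin-interface matrix protein (60.1 ± 49.5 to 1.61 ± 0.785 CPM, log2 fold change -5.22, SE 0.86), and the cytokine IL36B (94.7 ± 74.4 to 3.72 ± 2.01 CPM, log2 fold change -4.67, SE 0.83). Also lower were the actin-regulating MARCKSL1 (23.1 ± 16.7 to 1.32 ± 0.479 CPM, log2 fold change -4.12, SE 0.59) and the cancer-testis gene MAGEC2 (log2 fold change -3.40, SE 0.72). They were followed within the rule by the nucleotide hydrolase DNPH1 (-2.87), the synaptic scaffold gene BEGAIN (-2.81), the antisense transcript NECTIN3-AS1 (-2.77) and the endosomal EHD3 (39.1 ± 17.8 to 6.79 ± 2.05 CPM, log2 fold change -2.52, SE 0.34). Against control replicate 1 alone the losses of EMILIN2 (-0.92), IL36B (-1.24), MAGEC2 (-0.44) and BEGAIN (-0.21) no longer passed, while MARCKSL1 (-1.56), DNPH1 (-1.16), NECTIN3-AS1 (-1.30) and EHD3 (-1.46) did.

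DNA replication genes rose as a list, with 11 of 30 members higher over all genes and 14 adjusted over the list alone (median log2 fold change 0.47, adjusted p 4.7e-08, and 0.869 with an estimated correlation). RFC3, a clamp-loader subunit, rose by 0.86 log2 units (SE 0.13, 55.4 ± 3.20 to 100 ± 14.9 CPM) and the cyclin CCNE2 by 1.00 (SE 0.18). Further members that rose were the replication initiation factor MCM10 by 0.75 (SE 0.16) and the ribonucleotide reductase subunit RRM1 by 0.64 (SE 0.13). All 4 of these passed against control replicate 1 alone, although the list did not (adjusted p 0.761). Of the mitosis genes 4 of 31 were higher, 5 adjusted over the list alone (median 0.35, adjusted p 9.6e-04, and 0.464 with an estimated correlation). CDK1, the mitotic kinase, rose from 158 ± 10.7 to 294 ± 50.04 CPM (log2 fold change 0.90, SE 0.14), the checkpoint kinase TTK by 0.69, and NUSAP1 and CCNB2 by 0.80 and 0.57. CCNB2 no longer passed against control replicate 1 alone (adjusted p 0.547).

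Of 25 p53 targets 6 were lower and 1 higher, with 12 lower adjusted over the list alone (median -0.41, adjusted p 0.0052, and 0.869 with an estimated correlation). The antiproliferative BTG2 fell from 11.6 ± 1.95 to 3.63 ± 1.82 CPM (log2 fold change -1.68, SE 0.33), and the death receptor TNFRSF10B by 0.64 (SE 0.14). Lower as well were the AKT inhibitor PHLDA3 by 0.70 (SE 0.18) and the mitochondrial reductase FDXR by 0.65 (SE 0.19). Each also passed against control replicate 1 alone. Lists of ribosomal proteins (median 0.43, adjusted p 4.2e-05, RPL14 0.77) and of nuclear-encoded oxidative phosphorylation (median 0.26, adjusted p 0.0391, SDHD 0.76) moved with the library difference of the controls. Their medians were -0.37 and -0.36 against control replicate 1 alone, where RPL14 no longer passed (adjusted p 0.372). With an estimated correlation both stood at an adjusted p of 0.869.

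The lists nearest to the target did not pass in U87. Chaperone-mediated autophagy had a median of 0.18 (adjusted p 0.236, 2 of 22 members higher and 1 lower). The same held for lysosomal genes (median 0.09, adjusted p 0.379, 3 of 33 higher and 5 lower) and macroautophagy (median 0.02, adjusted p 0.379, 5 of 34 higher and 1 lower). Among their members, named after the values were seen, the sorting nexin SNX10 rose by 3.40 log2 units (SE 0.41, 0.266 ± 0.295 to 2.88 ± 0.763 CPM) and the protease CTSB by 0.68 (SE 0.14). Of the 1144 genes called in U87, 261 were also called in the same direction against control replicate 1 alone, 159 of them higher and 102 lower. Fitting the 6 U87 libraries alone left 1 higher and 0 lower gene in edgeR. In that fit 350 and 813 genes passed an unadjusted p under 0.05 with at least a 2-fold change and DESeq2 called 229 and 445. The edgeR calls in U87 thus depended on a spread shared with the other groups.

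In U251 with hairpin 1812, CXCL8, ATF3 and 4 of 35 interferon-response genes rose, while GFAP, the integrin genes ITGB4 and ITGB8 and basement membrane collagens fell. The neutrophil chemokine CXCL8 rose from 186 ± 38.6 to 633 ± 54.5 CPM (n = 3 and 3, log2 fold change 1.76, SE 0.21, adjusted p 0.00162). The stress-induced transcription factor ATF3 rose from 17.5 ± 2.83 to 49.9 ± 0.438 CPM (log2 fold change 1.51, SE 0.18, adjusted p 0.00142). GFAP, the astrocyte intermediate filament, fell from 116 ± 24.99 to 17.6 ± 7.53 CPM (log2 fold change -2.72, SE 0.27, adjusted p 2.7e-04). In total 42 genes were called higher and 41 lower, or 59 and 66 with a replicate block in the fit. Without U251 control replicate 1 the counts were 104 and 115, without control replicate 2 or 3 they were 9 and 5 or 8 and 5, and without hairpin replicate 1, 2 or 3 they were 18 and 20, 8 and 5, or 9 and 3.

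Other genes with large gains were the IGF-binding IGFBP6 (28.2 ± 3.02 to 91.9 ± 2.74 CPM, log2 fold change 1.71, SE 0.14) and the growth-cone membrane protein BASP1 (7.14 ± 0.230 to 23.3 ± 2.31 CPM, log2 fold change 1.71, SE 0.13). Gains also came from the T-cell chemokine CXCL11 (2.13, SE 0.38) and the secretory chaperone SCG5 (2.10, SE 0.38). Besides GFAP, ITGB4 and LAMP2, the losses named by the rule, with its limit of 5 FPKM, were DENND11 (-1.35, SE 0.24) and the basement membrane collagens COL18A1 (-1.27, SE 0.24) and COL4A2 (-1.15, SE 0.22). The rule also named the hedgehog pathway factor GLI3 (-1.10, SE 0.22) and the endothelial adhesion gene HEG1 (-1.07, SE 0.21). Against control replicate 1 alone DENND11 (-0.53), COL18A1 (adjusted p 0.0606), COL4A2 (-0.52) and HEG1 (adjusted p 0.0983) no longer passed.

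Immediate early genes rose as a list (3 of 24 higher, 4 adjusted over the list alone, median 0.42, adjusted p 4.5e-08), with the phosphatase DUSP5 at 1.34 (SE 0.17) and MYC at 0.68 (SE 0.13) beside ATF3. This held with an estimated correlation (adjusted p 0.00184). Interferon-response genes rose (4 of 35 higher, 10 adjusted over the list alone, median 0.28, adjusted p 5.3e-07, and 0.409 with an estimated correlation). They were led by the antiviral RSAD2 (46.8 ± 26.8 to 254 ± 17.8 CPM, log2 fold change 2.44, SE 0.44), OASL (28.9 ± 8.94 to 100 ± 34.3 CPM, 1.79, SE 0.30), IFIT2 (1.46, SE 0.30) and the ubiquitin-like ISG15 (258 ± 7.44 to 585 ± 22.5 CPM, 1.18, SE 0.21). The median of this list was 1.09 against control replicate 1 alone. MHC class I antigen presentation rose as a list with 9 of 16 members higher and 1 lower adjusted over the list alone (median 0.72, adjusted p 3.1e-04, and 0.409 with an estimated correlation). Over all genes 0 members passed in edgeR, 9 were higher at an unadjusted p under 0.05 and 3 were higher by DESeq2. NF-kB and inflammatory cytokine genes rose (CXCL8 over all genes, 4 of 28 higher adjusted over the list alone, median 0.41, adjusted p 2.8e-04, and 0.409 with an estimated correlation).

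Integrated stress response genes rose (3 of 29 higher, median 0.30, adjusted p 3.2e-04, and 0.409 with an estimated correlation), with ATF3, the secreted STC2 (1.03, SE 0.19) and the pro-apoptotic factor DDIT3 (0.74, SE 0.14). Against control replicate 1 alone the list stood at an adjusted p of 0.54. Hypoxia genes rose as a list (1 of 24 higher over all genes, ADM at 0.97, and 5 adjusted over the list alone, median 0.21, adjusted p 0.00428, and 0.659 with an estimated correlation). Astrocyte markers fell (GFAP and the glutamate transporter SLC1A3 at -0.71, SE 0.13, 2 of 11 members, median -0.22, adjusted p 1.1e-04, and 0.0207 with an estimated correlation). Mitosis genes fell slightly (median -0.29, adjusted p 6.8e-06, and 0.0359 with an estimated correlation). Of these 3 of 31 were lower adjusted over the list alone, and over all genes 0 in edgeR, 13 at an unadjusted p under 0.05 and 5 by DESeq2. Integrins fell (2 of 15 lower, 3 adjusted over the list alone, median -0.39, adjusted p 2.6e-04, and 0.331 with an estimated correlation). The hemidesmosomal ITGB4 fell from 176 ± 12.9 to 77.3 ± 4.36 CPM (-1.19, SE 0.15) and the TGF-beta-activating ITGB8 by 0.79 log2 units (SE 0.16). Extracellular matrix genes fell (1 of 38 lower, 13 adjusted over the list alone, median -0.53, adjusted p 1.2e-06, and 0.409 with an estimated correlation). The list did not pass against control replicate 1 alone (adjusted p 0.325). Of the single genes named here, MYC (adjusted p 0.105), STC2 (0.0591), DDIT3 (0.143), SLC1A3 (0.0777) and ITGB8 (0.0548) no longer passed there. With the library type of control replicates 2 and 3 as a term, an alternative also chosen after seeing the data, the lists of MHC class I genes (adjusted p 0.0706), the integrated stress response (0.425), integrins (0.352) and extracellular matrix (0.841) no longer passed.

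Several abundant classes moved together in U251 with hairpin 1812. Mitochondrially encoded transcripts, which took 3.26% to 3.62% of counts in control replicates 2 and 3 against 1.22% to 2.99% elsewhere, were lower (median -0.82, adjusted p 6.0e-07, 7 of 13 lower adjusted over the list alone). Their median was -0.15 against control replicate 1 alone, and the list no longer passed with the library type term (adjusted p 0.885). Ribosomal proteins (median 0.34), nuclear-encoded oxidative phosphorylation (0.33), proteasome subunits (0.28), NRF2 targets (0.35) and glycolysis (0.23) were higher as lists. Lists of stem and proneural genes (-0.32) and fatty acid metabolism (-0.09, with the acetyl-CoA carboxylase ACACA at -0.62 and an adjusted p of 0.217 against control replicate 1 alone) were lower. With an estimated correlation none of these 8 lists passed (adjusted p 0.124 to 0.709). The ribosomal list passed in the other direction against control replicate 1 alone (median -0.15). Oxidative phosphorylation (median -0.09, adjusted p 0.116), proteasome subunits (-0.03, adjusted p 0.983) and NRF2 targets (-0.03, adjusted p 0.147) no longer passed there. With the library type term ribosomal, oxidative phosphorylation and proteasome lists passed as lower, and NRF2 targets (adjusted p 0.113) and glycolysis (0.624) no longer passed. Chaperone-mediated autophagy (median 0.08, adjusted p 0.457), lysosomal genes (0.08, adjusted p 0.709) and macroautophagy (0.13, adjusted p 0.111) did not pass with all controls. GFAP, which is also on the list of chaperone-mediated autophagy, was its 1 passing member of 22 there. With the library type term chaperone-mediated autophagy passed as lower (adjusted p 0.00831). Lysosomal genes (0.226) and macroautophagy (0.433) did not pass with the term.

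In U251 with hairpin 1813, few genes passed, and CXCL8 rose while LAMA4 fell. CXCL8 went from 186 ± 38.6 to 711 ± 172 CPM (n = 3 and 3, log2 fold change 1.94, SE 0.21, adjusted p 0.00374), and LAMA4 from 135 ± 15.9 to 67.7 ± 1.96 CPM (-0.99, SE 0.12, adjusted p 0.00515). BASP1 rose to 13.2 ± 0.598 CPM (0.88, SE 0.13, adjusted p 0.0181), and PLEKHG1 fell from 57.6 ± 4.35 to 31.2 ± 2.06 CPM (-0.89, SE 0.14, adjusted p 0.0451). The 5 genes called at a 2-fold change were CXCL8, the transcript AL355075.4 and, on the lower side and outside the naming rule, the collagen COL14A1 (-2.27, SE 0.27), the cadherin-family FAT2 (-3.10, SE 0.47) and the hyaluronan-degrading CEMIP (-2.14, SE 0.29). With a replicate block 3 genes were higher and 6 lower, and without U251 control replicate 1 43 and 67 were. The lower genes numbered 1 without control replicate 2, 1 without hairpin replicate 2 and 0 without hairpin replicate 3. Against control replicate 1 alone BASP1 (adjusted p 0.0702) and PLEKHG1 (0.0875) no longer passed.

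Extracellular matrix genes fell as a list with hairpin 1813 (LAMA4 over all genes, 12 of 38 lower adjusted over the list alone, median -0.56, adjusted p 1.1e-09). Their median was -0.13 against control replicate 1 alone, and the list no longer passed with the library type term (adjusted p 0.246) or an estimated correlation (0.568). At the preset correlation so did integrins (median -0.40, 2 of 15 lower adjusted over the list alone), mitochondrially encoded transcripts (-0.69) and interferon-response genes (median -0.36, adjusted p 0.00149). Interferon-response genes rose against control replicate 1 alone (median 0.30), while integrins (median 0.03, adjusted p 0.287) and mitochondrially encoded transcripts (median 0.01, adjusted p 0.917) no longer passed. NF-kB and inflammatory genes rose (CXCL8 over all genes, 3 of 28 adjusted over the list alone, median 0.54, adjusted p 3.1e-05). Lists that also rose were ribosomal proteins (median 0.64, adjusted p 1.2e-17), nuclear-encoded oxidative phosphorylation (0.45), proteasome subunits (0.44), NRF2 targets (0.42), glycolysis (0.28) and the integrated stress response (0.26). Of these, oxidative phosphorylation (adjusted p 0.335), NRF2 targets (0.967) and the integrated stress response (0.917) no longer passed against control replicate 1 alone. With the library type term only NF-kB and inflammatory genes kept their call, and mitochondrially encoded transcripts passed as higher. With an estimated correlation none of these 11 lists passed (adjusted p 0.568 to 0.671). Lists of chaperone-mediated autophagy (median 0.16, adjusted p 0.353), lysosomal genes (-0.06, adjusted p 0.368) and macroautophagy (0.13, adjusted p 0.113) did not pass with all controls. With the library type term lysosomal genes passed as lower (adjusted p 4.0e-04), while chaperone-mediated autophagy and macroautophagy did not pass (0.441 for each).

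**Figure D3:**
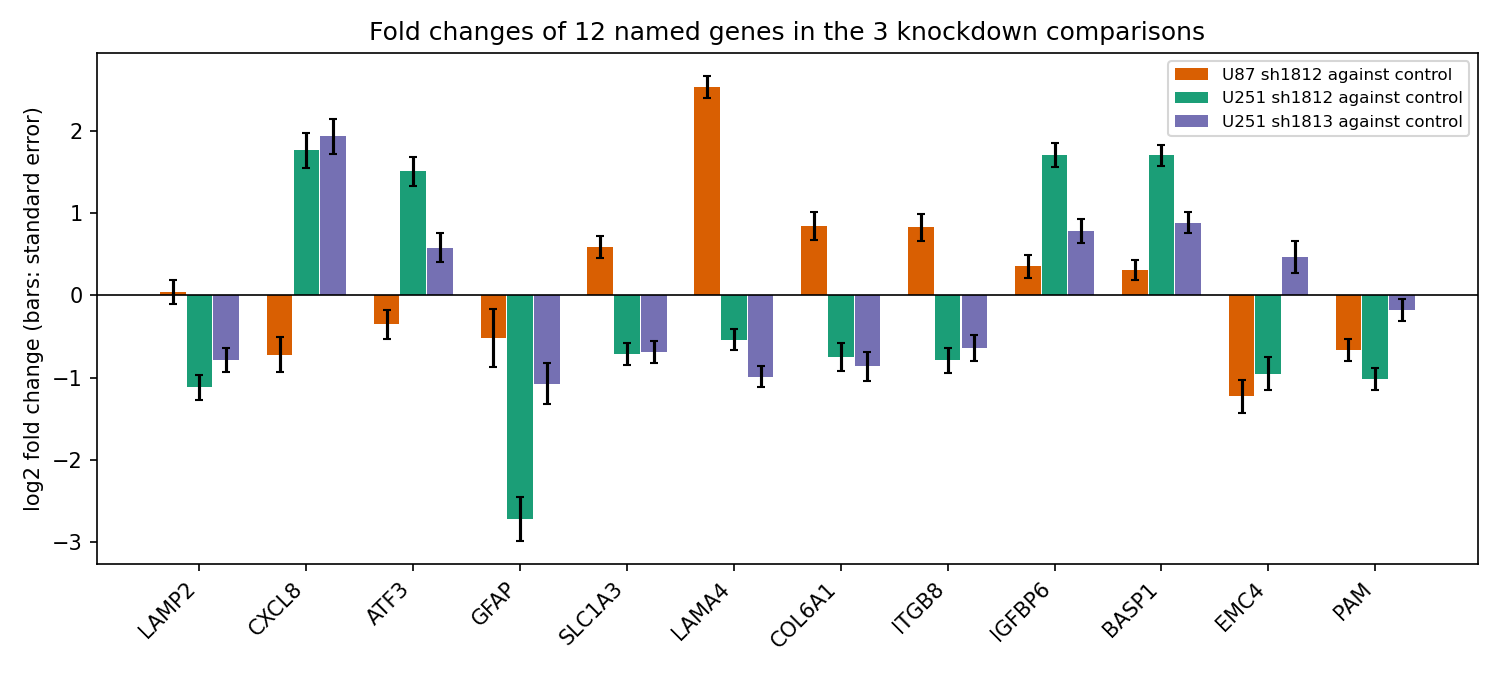
Log2 fold change against the control libraries of the same line (bars) with standard errors (lines) for 12 genes chosen after their values were seen, in U87 with hairpin 1812 and in U251 with hairpin 1812 and 1813, 3 libraries per group. CXCL8 is at -0.72, 1.76 and 1.94, LAMA4 at 2.53, -0.54 and -0.99, and GFAP at -0.52, -2.72 and -1.08.

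Fold changes of the hairpins in U251 correlated, in part through their shared controls. Their log2 fold changes across 16841 genes gave a Pearson r of 0.635 and a Spearman correlation of 0.689, with genes not independent replicates. Because the hairpins share their controls, unchanged groups simulated against the same controls gave an r of 0.480 (SD 0.0121, 50 simulations), and the observed covariance of 0.197 exceeded the simulated 0.0856 by 0.111. The simulation leaves out the library type of control replicates 2 and 3, a shift that both fold changes share, so the excess cannot be assigned to the hairpins. CXCL8 and AL355075.4 were called higher with both hairpins and 2 genes lower with both, against 0 in either direction in every simulation. GFAP, at -2.72 with hairpin 1812, was at -1.08 (SE 0.25) with hairpin 1813, which did not pass.

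Direct comparison of the hairpins in U251 showed higher interferon-response and immediate early genes, and lower mitosis genes, with hairpin 1812 than with 1813. Of 35 interferon genes 34 had a positive difference, 1 passed over all genes and 21 adjusted over the list alone (median 0.71, adjusted p 2.9e-34, and 0.0423 with an estimated correlation). IFIT2 was at 166 ± 35.0 against 47.1 ± 8.68 CPM (log2 difference 1.81, SE 0.31, n = 3 and 3). Immediate early genes (median 0.34, adjusted p 2.6e-10, 4 of 24 adjusted over the list alone), mitosis genes (-0.25, adjusted p 2.8e-11, 3 of 31) and astrocyte markers (-0.07, adjusted p 0.00265, with GFAP at -1.65, SE 0.26) also held with an estimated correlation (adjusted p 7.5e-04, 0.0041 and 0.0423). MHC class I genes were higher with hairpin 1812 (15 of 16 positive, 3 passing adjusted over the list alone, median 0.44, adjusted p 6.8e-09, and 0.195 with an estimated correlation). Also passing at the preset correlation alone were hypoxia genes (0.25), histones (0.24), ribosomal proteins (-0.31), mitochondrially encoded transcripts (-0.26), chaperone-mediated autophagy (-0.10), oxidative phosphorylation (-0.12), proteasome subunits (-0.16) and DNA replication (-0.10).

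Among single genes, the hairpins differed at the carboxypeptidase CPA4 (465 ± 104 with 1812 against 94.4 ± 18.9 CPM with 1813, log2 difference 2.30, SE 0.35, adjusted p 0.0235) and at IFIT2. Higher as well were the acid phosphatase ACP5 (28.7 ± 4.30 against 10.3 ± 3.17 CPM, 1.48, SE 0.21), the reductase DHRS2 (231 ± 19.7 against 84.2 ± 33.0 CPM, 1.45, SE 0.25) and BEX1 (1.38, SE 0.24). On the lower side were EMC4, a subunit of the endoplasmic reticulum membrane complex (62.2 ± 4.42 against 166 ± 6.55 CPM, -1.42, SE 0.20) and the hexosamine enzyme GFPT2 (28.5 ± 0.958 against 68.3 ± 11.7 CPM, -1.26, SE 0.18). They were joined by GFAP, the peptide-amidating PAM (-0.83, SE 0.13) and, outside the naming rule, the metalloproteinase inhibitor TIMP3 (-1.40, SE 0.19). The transcriptional regulator CITED2 (0.96), IGFBP6 (0.93) and BASP1 (0.82), also outside the rule, passed below a 2-fold difference. The number of genes called fell from 9 to 1, 0 or 2 without hairpin 1812 replicate 1, 2 or 3. It fell to 4, 0 or 1 without hairpin 1813 replicate 1, 2 or 3. With a replicate block IFIT2 and DHRS2 no longer passed.

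Across both lines and both hairpins, 1 gene was called in the same direction in all 3 knockdown comparisons. This was AL355075.4 (ENSG00000259001, chromosome 14, 20343048 to 20343685, minus strand), which contains RPPH1, the RNA component of RNase P, on the same strand and overlaps the start of PARP2 on the other strand. RPPH1 itself had 0 counts in every library, and the counting strand was not stated. AL355075.4 rose from 0.200 ± 0.208 to 132 ± 84.4 CPM in U87 (log2 fold change 9.32, SE 0.65, adjusted p 4.4e-06). In U251 it rose from 10.3 ± 2.98 CPM in control to 229 ± 52.0 CPM with hairpin 1812 (4.48, SE 0.45, adjusted p 2.7e-04) and 135 ± 31.1 CPM with hairpin 1813 (3.71, SE 0.43, adjusted p 0.00374). Without U87 control replicate 1 the shared genes numbered 36, and without U251 control replicate 1 they numbered 5. Among single genes, hairpin 1812 had little in common between the lines beyond this. Fold changes in U87 and U251 correlated at r 0.162 across genes, and those in U87 correlated with hairpin 1813 in U251 at r 0.196. In both lines 4 genes were called higher (0.873 by independent lists, Fisher's exact p 0.011) and 3 lower (1.93 by independent lists, Fisher's exact p 0.442). The difference among control replicates, which correlated between the lines, can add to these correlations and shared calls. Independent lists leave it out. Besides AL355075.4, the shared genes, outside the naming rule, were DHRS2 (1.23 in U87, 1.49 in U251), the hyaluronan synthase HAS2 (1.27, 1.41) and TMEM158 (1.15, 1.54) on the higher side. On the lower side were SCUBE3 (-3.10, -2.36), CLIP3 (-1.32, -1.02) and SRGAP3 (-1.02, -1.36). With the library type term, interferon-response and hypoxia lists passed as higher with hairpin 1812 in both lines. Their adjusted p was 4.0e-08 and 8.8e-04 in U87 and 8.2e-21 and 1.2e-08 in U251. With all controls neither list passed in U87 (adjusted p 0.0654 and 0.488). Mitosis and DNA replication lists passed with the term as higher in U87 and lower in U251.

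The effect of hairpin 1812 differed between U87 and U251 at 545 genes, 243 with a positive and 302 with a negative difference, and some genes moved in opposite directions. CXCL8 fell in U87 (136 ± 26.0 to 82.9 ± 12.3 CPM, log2 fold change -0.72, SE 0.21, adjusted p 0.0349) and rose in U251 (difference -2.48, SE 0.30, adjusted p 0.00119). LAMA4 rose in U87 and stood at -0.54 (SE 0.12, adjusted p 0.0549) in U251 (difference 3.07, SE 0.18, adjusted p 9.1e-07). SLC1A3 and ITGB8 rose in U87 (0.59 and 0.83) and fell in U251 (-0.71 and -0.79), and DDIT3 fell in U87 (-0.54) and rose in U251 (0.74). EFEMP1 differed by 4.93 (SE 0.53), IL36B by -7.54 (SE 1.29), the interleukin-36 antagonist IL36RN by -4.38 (SE 0.80) and SNX10 by 3.85 (SE 0.48). As a list, mitosis genes had a more positive effect of the hairpin in U87 than in U251 (8 of 31 passing over all genes, 12 adjusted over the list alone, median difference 0.68, adjusted p 4.5e-10, and 0.0133 with an estimated correlation), and immediate early genes a more negative one (median -0.55, adjusted p 0.00121, and 0.0405 with an estimated correlation). Of the 545 genes, 231 were also called in the same direction against control replicate 1 alone. Leaving out 1 library of these 4 groups gave 211 genes (without U251 hairpin 1812 replicate 2) to 2019 genes (without U87 control replicate 1), and the count stayed within 1.5-fold only without U87 hairpin replicate 2 or U251 control replicate 1.

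Between the control libraries of the lines, 33 of 35 interferon-response genes and 16 of 23 stem and proneural genes were higher in U251, and 12 of 22 glycolysis genes and 18 of 25 p53 targets were higher in U87. SOX2, a stem cell transcription factor, stood at 173 ± 26.7 CPM in U251 and 0.174 ± 0.0946 CPM in U87 (n = 3 and 3, log2 difference 9.88, SE 0.38, adjusted p 7.9e-11). LAMP2 was itself higher in U251 (1.42, SE 0.15, adjusted p 2.2e-06). LDHA, the lactate dehydrogenase, was at 38.6 ± 7.54 CPM in U251 and 3085 ± 451 CPM in U87 (-6.32, SE 0.20). The list of p53 targets no longer passed against control replicate 1 alone (adjusted p 0.0636). In total 2642 genes were higher and 2685 lower in U251.

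In the control libraries, genes without a count in U87 were PNMA8A (34.1 ± 6.45 CPM in U251), the homeobox genes HOXB9 (26.3 ± 4.16 CPM) and IRX1 (22.5 ± 6.22 CPM), the fatty acid elongase ELOVL2 (23.1 ± 3.92 CPM) and SOX21 (14.2 ± 2.47 CPM). In the order PNMA8A, HOXB9, IRX1, ELOVL2 and SOX21 they were at least 514-, 396-, 338-, 348- and 215-fold higher in U251, with the floor over the group. The cytokine TNFSF9 (26.8 ± 10.7 CPM in U87), the bHLH factor MSC (23.3 ± 8.72 CPM) and the metallothionein pseudogene MT1L (18.9 ± 4.17 CPM) had no count in U251 control. They were at least 486-, 423- and 343-fold lower there. FOXD1, a forkhead factor, was at 89.1 ± 8.01 CPM in U87 with 0.0195 CPM in U251 (ratio 2.1e-04, exact 95% interval 5.2e-06 to 0.00115). The neurexin gene NRXN2 was at 71.2 ± 24.3 CPM (ratio 2.6e-04, exact 95% interval 6.5e-06 to 0.00144).

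Of 35 interferon genes 33 were higher in U251, the same number adjusted over the list alone (median 3.15, adjusted p 4.2e-17, and 0.48 with an estimated correlation). BST2 was at 392 ± 43.9 against 0.822 ± 0.254 CPM (8.89, SE 0.32), IFI27 at 9.06 (SE 0.43), IFI6 at 5.75 (SE 0.29) and ISG15 at 4.66 (SE 0.24). Of 23 stem and proneural genes 16 were higher and 2 lower, with 17 higher adjusted over the list alone (median 1.93, adjusted p 4.0e-08, and 0.00364 with an estimated correlation). Among them were the neural factors POU3F2 (7.28, SE 0.34), SOX9 (3.89, SE 0.21) and SOX4 (3.01, SE 0.21). Of 22 glycolysis genes 12 were lower and 2 higher, with the same numbers adjusted over the list alone (median -0.81, adjusted p 0.00534, and 0.832 with an estimated correlation). They included the aldolase ALDOC (-5.64, SE 0.39), ENO2 (-1.34, SE 0.16) and the hexokinase HK1 (-1.22, SE 0.13). Of 25 p53 targets 18 were lower and 3 higher, with the same numbers adjusted over the list alone (median -0.97, adjusted p 0.0372, and 0.832 with an estimated correlation). The largest among those named were PHLDA3 (-2.90, SE 0.19), DDB2 (-2.13, SE 0.28), TP53INP1 (-1.81, SE 0.25) and TIGAR (-1.44, SE 0.19). These list tests between the lines were chosen after seeing the data.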

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

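All tests of explanations in this part, and the counts of other splits of the libraries, were chosen after the results were seen, while the test of the difference between the lines was planned.

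The large number of genes called in U87 with hairpin 1812 (1144) moved with a difference among the control libraries. Genes called lower stood at a median log2 of -0.59 against control replicate 1 and -2.04 against control replicates 2 and 3, and 72.9% of them lay within 2-fold of control replicate 1. With a term for the library type of control replicates 2 and 3, 32.2% of the lower genes were still called. Most lower calls thus went with the difference among the controls, whose source no label states. Genes called higher stood at medians of 1.25 and 1.95, with 33.4% within 2-fold of control replicate 1. With the term 63.7% of them were still called, and against control replicate 1 alone 159 of 350. The term is shared by both lines, while control replicate 1 differed from the others at 5464 genes in U87 and 1556 in U251, so the library type stays open as a source of the higher calls. In total 479 of the 1144 genes were called with the term and 261 against control replicate 1 alone. A trend with gene length alone is argued against, since 1151 genes were called after it was removed. A knockdown library mislabelled as control replicate 1 was not excluded. The AL355075.4 count of that library was 0, but this gene was picked for being called higher in all 3 knockdown comparisons. Its link to the hairpins is also a hypothesis, so the count cannot decide. In the same direction 250 genes were called with all controls, with control replicate 1 alone and with the term. For these an effect of hairpin 1812 cannot be told apart from the library type or from a difference in culture or clone, since the fit without control replicates 2 and 3 rests on a lone U87 control and the term assumes the same shift in both lines.

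The 6 U87 libraries allow 10 splits, too few for a share under 0.05. Including the real split with 1144, 3 gave at least as many calls, and the highest other gave 1185. Control replicates 2 and 3 were set with 1 hairpin library against the rest in 3 splits. These gave 1160 calls with hairpin replicate 1, 1 call with replicate 2 and 1185 with replicate 3. Setting control replicates 2 and 3 apart thus gave counts as high as the real one with hairpin replicates 1 and 3. The splits therefore cannot tell the library type from the hairpin. Against control replicate 1 alone, 806 genes were higher and 262 lower.

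AL355075.4 was higher in all 9 knockdown libraries than in the control libraries of its line, and its gain was larger in U87 than in U251 by 4.84 log2 units, a difference that passed the test between the lines. That difference rests on 9 counts over the 3 U87 control libraries and ranged from 2.63 to 9.88 over the alternatives, while the level reached was lower in U87 (132 CPM) than in U251 (229 CPM). The neighbour of AL355075.4, PARP2, did not rise, with a largest log2 fold change in the 3 knockdown comparisons of 0.06 (SE 0.17). PARP2 is a separate gene on the other strand and need not rise with AL355075.4. Activation of the chromosomal locus therefore stays open. Of the exonic bases of AL355075.4 outside RPPH1, 91.1% lie upstream of RPPH1, where its promoter is. Reads from a hairpin vector that carries such a promoter sequence may therefore have been counted as AL355075.4, but the labels name no vector or promoter and this stays a hypothesis. The test came from annotation and not from reads. RPPH1 lies wholly inside AL355075.4 and had 0 counts in every library. How reads overlapping both genes were counted was not examined, so these 0 counts decide nothing here. In 100 drawn splits, only the real one gave a gene called in the same direction in all 3 knockdown comparisons (1 gene, highest other 0). Such splits mix control and hairpin libraries, which widens the spread within groups. In U251 alone the mixed splits called 0 genes for either hairpin, so this comparison cannot exclude chance.

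LAMP2 was not lower in U87 with hairpin 1812, and its fold change differed from that in U251 by 1.16 log2 units, which passed the test between the lines. The library type of control replicates 2 and 3 is argued against as what hid a loss, since LAMP2 stood at a log2 fold change of 0.29 with the library type term and 0.45 against control replicate 1 alone. An exchange of the U87 control and hairpin labels was not excluded. The lowest level of AL355075.4 in the U87 hairpin libraries was 76.6 CPM. This gene was picked for being higher in all 3 knockdown comparisons, so its level cannot decide on the labels. A loss of LAMP2A under unchanged other isoforms stays open, since the 95% interval allows a loss of up to 17.6% of the total and gene counts do not separate isoforms. What made the effect on LAMP2 weaker in U87 was not tested further.

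The remaining results in this part are differences between the lines in the effect of hairpin 1812, each given as the log2 fold change in U87 minus that in U251, and each passed the planned test of that difference. In total 545 genes were called, with 5 of 100 drawn splits giving at least as many, so chance cannot be excluded for the count; the highest other split gave 2350 genes, several times the real count. Besides AL355075.4 and HOXB9, the largest differences under the naming rule, with its limit of 5 FPKM, were EFEMP1 4.93, SNX10 3.85 and ZNF260 3.34. On the other side they were IL36B -7.54, LDOC1 -4.81, EMILIN2 -4.77, IL36RN -4.38 and ZNF114 -4.29. For HOXB9 the fit gave 4.78, but it had 0 counts in U87 control and 0.262 ± 0.170 CPM with the hairpin, at least 3.94-fold over the floor. Its fitted difference ranged from -0.12 to 5.15 over the alternatives. HOXB9 (adjusted p 0.18), EMILIN2 (0.568) and ZNF114 (0.193) no longer passed against control replicate 1 alone.

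For the lists, only mitosis and immediate early genes also passed with an estimated correlation, where the others stood at an adjusted p of 0.175 (astrocyte markers) or 0.567 (the other 7). The difference was positive for cell cycle genes. The replication list had a median difference of 0.43, with RFC3 0.88, MCM10 1.04 and CCNE2 1.06, and the mitosis list a median of 0.68, with TTK 0.80, KIF20A 1.03, BUB1B 0.74 and ECT2 1.05. The p53 target list had a median of -0.53, with GADD45A -1.34, PHLDA3 -1.21 and TP53I3 -1.35. The replication list (adjusted p 0.0501) and the p53 list (0.0872) no longer passed against control replicate 1 alone, nor did RFC3 (0.0537), TTK (0.122), KIF20A (0.095), BUB1B (0.0504) and TP53I3 (0.477).

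For matrix and adhesion genes the difference was positive, while in U87 itself neither list passed with all controls (adjusted p 0.447 and 0.379). Both passed there as higher against control replicate 1 alone (adjusted p 1.1e-06 and 0.00637) and with the library type term (9.6e-07 and 0.0138). The extracellular matrix list had a median difference of 0.18, with LAMA4 3.07, COL6A1 1.596, PLAU 1.28 and COL4A1 2.95, and the integrin list a median of 0.35, with ITGB8 1.62, ITGA7 2.25, ITGB4 1.49 and ITGA11 3.19. Astrocyte markers had a median of 0.27, with SLC1A3 1.30, GFAP 2.20 and AGT 4.13, and mitochondrially encoded transcripts a median of 0.87, with MT-CO3 1.56 and MT-CO2 1.08. The astrocyte list (adjusted p 0.164), AGT (0.258), PLAU (0.0809), COL4A1 (0.189) and ITGA11 (0.205) no longer passed against control replicate 1 alone.

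For stress and inflammatory genes the difference was negative, while in U87 itself none of these lists passed with all controls (adjusted p 0.737, 0.12 and 0.379 in the order below). The integrated stress response passed there as lower against control replicate 1 alone (adjusted p 0.00242) and with the library type term (8.9e-05), and NF-kB genes against control replicate 1 alone (0.00637). Immediate early genes had a median difference of -0.55 with ATF3 -1.86, the integrated stress response a median of -0.31 with DDIT3 -1.28, SLC3A2 -1.56 and TRIB3 -1.72, and NF-kB and inflammatory genes a median of -0.83 with CXCL8 -2.48, CXCL3 -2.17, IL1A -2.31 and CCL20 -3.24. IL1A (adjusted p 0.229) and CCL20 (0.394) no longer passed against control replicate 1 alone.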

How the results depend on the processing

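The counts of called genes, the correlation of the hairpins and the LAMP2 fold changes were each taken under every alternative. Of these values 192 stayed the same, 136 moved and 6 passed where they had not before. Counts stayed the same within 1.5-fold, and LAMP2 on the same side of the threshold without a reversed call. The correlation did so if its shift was smaller than the SD of the correlations with 1 library left out. Among named genes 2604 values kept direction and threshold, 544 lost the threshold, 1 gained it and 2 reversed, and among lists 1188 kept both, 143 lost the threshold and 10 reversed. Under median-of-ratios scaling and robust empirical Bayes all 15 counts, correlations and LAMP2 values stayed the same by this measure. LAMP2 kept its direction and an adjusted p under 0.05 in U251 with hairpin 1812 under every alternative run, with a fold change under 2 with the library type term (-0.90) and after removal of the gene length trend (-0.95). With an estimated correlation 10 of 61 list calls remained and 51 did not. Unless stated otherwise, the cause of a change was not tested.

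Limma on log2(FPKM + 1) called 147 genes higher and 148 lower in U87, 19 lower in U251 with hairpin 1812, 4 higher and 9 lower with hairpin 1813, 1466 higher and 1153 lower between the lines, 21 between the hairpins and 298 in the difference between the lines, with a hairpin correlation of 0.754. With log2(FPKM + 0.1) it called 374 lower in U87, 1 higher with hairpin 1813, 1549 lower between the lines, 14 between the hairpins and 0 shared genes. After quantile normalization it called 218 higher and 188 lower in U87, 8 higher and 7 lower with hairpin 1813, 1627 higher and 1583 lower between the lines and 18 between the hairpins (correlation 0.729). With log2(FPKM + 0.5), chosen after seeing the data, it called 200 higher and 235 lower in U87, 6 higher and 10 lower with hairpin 1813, 1368 lower between the lines and 21 between the hairpins (correlation 0.733). HOXB9, near the floor in U87, reversed in the difference between the lines to -0.12 with log2(FPKM + 1) and -0.018 with log2(FPKM + 0.5).

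Without a filter on low counts 548 genes were higher in U87, 136 higher and 179 lower in U251 with hairpin 1812, 40 and 120 with hairpin 1813, 77 between the hairpins, 1048 in the difference between the lines and 31 shared (correlation 0.512), and LAMP2 passed with hairpin 1813 (-0.78). A filter of 5 FPKM tested fewer genes and called 95 higher and 190 lower in U87, 26 lower in U251 with hairpin 1812, 856 higher and 951 lower between the lines and 231 in the difference between the lines (correlation 0.732). A filter of 1 FPKM, chosen after seeing the data, called 519 lower in U87 and 5 lower with hairpin 1813. Over genes with a mean of at least 5 FPKM the hairpin correlation was 0.762.

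With a replicate block 66 genes were lower in U251 with hairpin 1812 and 6 lower with hairpin 1813. Fitting only the groups compared called 1 gene higher and 0 lower in U87. It called 111 and 130 in U251 with hairpin 1812, 6 and 23 with hairpin 1813 and 98 between the hairpins. It called 285 in the difference between the lines and 0 shared (correlation 0.737), and LAMP2 passed with hairpin 1813 (-0.80). Since counts rose within U251 and fell in U87, fewer libraries alone do not explain the change. The main fit shares the spread of each gene over all groups. Control replicate 1 differed from control replicates 2 and 3 over 2-fold at 5464 genes in U87 and 1556 in U251. DESeq2 called 100 higher and 131 lower in U251 with hairpin 1812, 13 and 48 with hairpin 1813, 46 between the hairpins, 902 in the difference between the lines and 5 shared, and LAMP2 passed with hairpin 1813 (-0.81).

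The following were chosen after seeing the data. With control replicate 1 as the only control, where this lone library is assumed to vary like the other groups, 806 genes were higher and 262 lower in U87, 66 lower in U251 with hairpin 1812, 7 higher and 10 lower with hairpin 1813, 57 between the hairpins and 991 in the difference between the lines (correlation 0.786), and LAMP2 passed in U87 (0.45) and with hairpin 1813 (-0.71). The list medians of ribosomal proteins (-0.37) and oxidative phosphorylation (-0.36) in U87, ribosomal proteins in U251 with hairpin 1812 (-0.15) and interferon genes with hairpin 1813 (0.30) reversed. With the library type of control replicates 2 and 3 as a term, 319 genes were lower in U87, 147 higher and 72 lower in U251 with hairpin 1812, 16 and 11 with hairpin 1813, 34 between the hairpins, 1097 in the difference between the lines and 2 shared (correlation 0.734). The medians of ribosomal proteins (-0.15) and oxidative phosphorylation (-0.23) in U87, ribosomal proteins (-0.34), oxidative phosphorylation (-0.26) and proteasome subunits (-0.20) in U251 with hairpin 1812, and mitochondrially encoded transcripts with hairpin 1813 (0.24) reversed. Removal of the gene length trend left 23 lower in U251 with hairpin 1812 and 5 lower with hairpin 1813.

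Leaving out 1 library at a time gave 188 to 1348 higher and 327 to 2129 lower genes in U87, 8 to 104 and 3 to 115 in U251 with hairpin 1812, 2 to 43 and 0 to 67 with hairpin 1813, 2537 to 2884 and 2621 to 3029 between the lines, 0 to 4 between the hairpins, 211 to 2019 in the difference between the lines and 1 to 36 shared. The highest knockdown counts came without control replicate 1 of the line. The hairpin correlation ranged from 0.549 to 0.732, and LAMP2 from -0.12 to 0.14 in U87, -1.14 to -1.10 in U251 with hairpin 1812 and -0.81 to -0.76 with hairpin 1813, where it passed without U251 control replicate 1 (-0.81). Depth limits genes near 0: 3 counts over a group are the floor of every bound given.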

Other observations

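The tests in this part were chosen after the results were seen.

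A few genes that passed with hairpin 1812 in both lines differed between the hairpins. At an adjusted p under 0.05, 44 genes passed with hairpin 1812 in both lines, 27 of them in the same direction, and 4 of these also differed between the hairpins in U251: EMC4, PAM, DHRS2 and ACP5. DHRS2 did not pass against control replicate 1 alone in U87 or U251 (adjusted p 0.178 and 0.0705) and ACP5 did not pass in U251 (adjusted p 0.108). The difference of the hairpins at DHRS2 was also lost with a replicate block. PAM stood at log2 fold changes of -0.66 in U87 and -1.01 in U251 with hairpin 1812 and -0.18 with hairpin 1813, and ACP5 at 0.92, 0.98 and -0.50.

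EMC4 (ENSG00000128463, chromosome 15, 34225013 to 34230156) fell with hairpin 1812 from 137 ± 45.7 to 58.6 ± 8.03 CPM in U87 (n = 3 and 3, log2 fold change -1.23, SE 0.20) and from 120 ± 20.9 to 62.2 ± 4.42 CPM in U251 (-0.95, SE 0.20), and it fell against control replicate 1 alone as well (-1.70 and -1.21). With hairpin 1813 it stood at 0.46 (SE 0.20), which did not pass (adjusted p 0.353). No explanation was tested, because these genes were picked for passing in both lines and for differing between the hairpins.

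For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In U251 the real split called 83 genes with hairpin 1812, 5 with hairpin 1813 and 9 between the hairpins, and the highest other split called 0 in each case. Between the control lines the real split called 5327 genes and the highest other 0. Each of these real splits was the only 1 of its 10 to reach its count. The other splits mix libraries of the groups compared, which widens the spread within groups. Their 0 calls therefore cannot exclude chance.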
